A study of Homo sapiens with 9 samples.

How the data were processed

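RNA was measured on 9 Affymetrix human genome arrays of A549 cells, 3 with a control oligo, 3 with an oligo against MED23 and 3 with an oligo against ELK1. Per the labels, the 3 replicates of each knockdown carry different RNA interference oligos and are described as different cell lines, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridized. The group and replicate number of each sample come from its labels.

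The deposited values are intensities: probe set signals on a linear scale. The submitters' processing notes name RMA and MAS5, with no role or version. In the values themselves the 2% trimmed mean was about 500 on each array while other quantiles differed, as MAS5 scaling leaves them, and no step beyond that is known. A common scaling of this kind removes any change in total messenger RNA, and it lowers or raises every gene of an array alike. The genome build is not given in the sources used here, and no coordinates are reported. The signal of a dim probe set is uncertain, and no detection calls were used here.

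The signals were analysed as log2(value + 1), and the added 1 lowers the fold changes of dim genes slightly. It does not make their sizes lower bounds. With signals raised to the filter level given below, the log2 fold change of CGN in si-Med23 went from 2.96 to 1.16. Probe sets were named from the platform annotation, which lists 42898 of them, 41091 with 1 gene and 1801 with several, and 11721 had no gene named here. The 62 control probe sets were kept out of all gene tests. Of the identifiers, 41037 were found in a RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols changed. Each of 19775 genes was represented by the probe set with the highest mean over the 9 arrays among those with exactly 1 symbol. Genes whose probe set mean lay under the median of all probe set means (log2 6.05, a signal of 65.4) were left out, which left 12616.

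Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 fit of all 9 arrays with no block, so that the groups share an estimate of the spread. The contrasts were si-Med23 against si-Ctrl, si-Elk1 against si-Ctrl, and si-Med23 against si-Elk1. P-values were adjusted by Benjamini-Hochberg over the genes tested within a contrast, with a threshold of 0.05. MED23 and ELK1 were tested over all probe sets with no filter. No duplicated array was found, and no scan date or batch was used here. Control probe sets were compared with exact permutation tests.

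The design, tests, the alternatives not named below as added and the symbols of 23 gene lists were fixed before the data were examined. The matching of those symbols to the annotation was corrected after first results had been seen, since RPL13 had been taken through a synonym as MRPL13 and 3 other lists held a wrong match of this kind, and all results come from the corrected matching. The lists cover Mediator subunits, TCF and SRF factors, immediate-early genes, ERK pathway output, Ras pathway components, SRF-MRTF targets, G1/S and G2/M genes, p53 targets, apoptosis, interferon, NF-kB, NRF2, unfolded protein response, sterol synthesis, hypoxia and glycolysis, ribosomal proteins, epithelial, mesenchymal, TGF-beta and alveolar type II genes, and markers of blood and endothelial cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and members were also counted adjusted over the list alone. Medians are over the log2 fold changes of the members tested.

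The genes named were chosen by a rule. It takes the targeted genes, the 10 largest rises and 10 largest falls of each knockdown among genes that passed with no overlap between groups, up to 4 members of each list with the smallest p, the 10 shared genes with the largest smaller change, and the 5 highest and 5 lowest differences between the knockdowns. Overlap between the knockdowns was set beside that of independent lists and beside 100 simulations of unchanged groups against the same controls.

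The fit was tested on simulated data for si-Med23 against si-Ctrl with 200 of 12616 genes changed, in 20 draws. It recovered 9.40% of genes changed 1.5-fold, 60.7% of those changed 2-fold and 92.1% of those changed 4-fold, and 4.91% of calls were false. The real comparison called 39.8% of genes, a far larger share than was changed here. The adjusted threshold depends on that share, so these values do not measure recovery in the real si-Med23 comparison. Alternatives were no filter and a stricter filter at the 70th percentile, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, quantile normalization, median centring, a fit of only the 6 arrays compared, the replicate number as a block, array weights, a trended and robust prior, other thresholds, a pseudocount of 16, each array left out in turn, and camera with an estimated correlation or fry. Scaling on the poly-A spikes or the hybridization controls, adjustment of the targeted genes over the tested genes, the sizes of named genes with signals under the filter level raised to it, with no test, and a split of the control arrays between the knockdowns were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.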

Results

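Gene expression was measured on 9 Affymetrix arrays of A549 cells, a human lung adenocarcinoma line, grown in serum-containing medium with no treatment before the experiment. In 3 samples the cells carried a control oligo (si-Ctrl), in 3 an RNA interference oligo against MED23 (si-Med23) and in 3 an oligo against ELK1 (si-Elk1). MED23 is a tail subunit of Mediator, the complex that links transcription factors to RNA polymerase II, and ELK1 is an ETS transcription factor that ERK phosphorylates and that can contact MED23. The series asks about the need of lung cancer cells for MED23, and the arrays address which transcripts change when either factor is reduced. The 3 replicates of each knockdown are 3 different oligos, called A, B and C, so their spread includes differences between oligos. Nothing in the labels says that the control samples were separate cultures, and p-values then measure only the spread between these samples, which may be technical. On each array the probe set signals, deposited on a linear scale, had a median between 64.9 and 88.2. The number of arrays limits the precision. After 1 probe set per gene was taken and dim genes were left out, 12616 genes were tested.

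The targeted transcripts were examined first. The main MED23 probe set gave log2 signals of 9.27, 9.05 and 9.08 in si-Ctrl and of 6.79, 6.19 and 7.06 with the si-Med23 oligos A, B and C. The log2 fold change of MED23 was -2.46 ± 0.30 (SE, n = 3 arrays per group), which left 18.2% of the control signal, with a limma adjusted p = 0.0230 over all probe sets. Another MED23 probe set fell by 3.44 on the log2 scale (adjusted p = 0.0351). Its si-Med23 signals of 2.89, 5.58 and 5.47 all lay below the filter level of log2 6.05, so that size is uncertain. The other 3 MED23 probe sets had log2 fold changes of -2.21, -1.36 and -0.76 that did not pass, and the first and last of these had control means of 5.80 and 4.97, also below that level. The main ELK1 probe set gave 9.36, 9.61 and 9.29 in si-Ctrl and 7.07, 7.15 and 7.83 with the si-Elk1 oligos, so every si-Elk1 array lay below every control array. Its log2 fold change was -2.07 ± 0.29, or 23.8% of the control signal, but its adjusted p over all probe sets was 0.0728 and did not pass, nor did the other ELK1 probe sets, with log2 fold changes of -1.08 and -0.85. The last of these had a control mean of 4.38, below the filter level. Adjusted over the 12616 tested genes instead, an alternative added after the data were seen, ELK1 passed with a limma adjusted p = 0.00684 and MED23 with 0.00184. In the si-Elk1 samples MED23 read 8.87, 9.02 and 8.18 with oligos A, B and C (log2 fold change -0.44, adjusted p = 0.60). In the si-Med23 samples ELK1 had a log2 fold change of 0.54 (adjusted p = 0.286). The MED23 call was lost without si-Ctrl replicate 1, 2 or 3 (adjusted p = 0.0715, 0.0672 and 0.0842) and without si-Med23 oligo B (0.0511). It was also lost with the replicate number as a block, as given below.

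**Figure D1:**
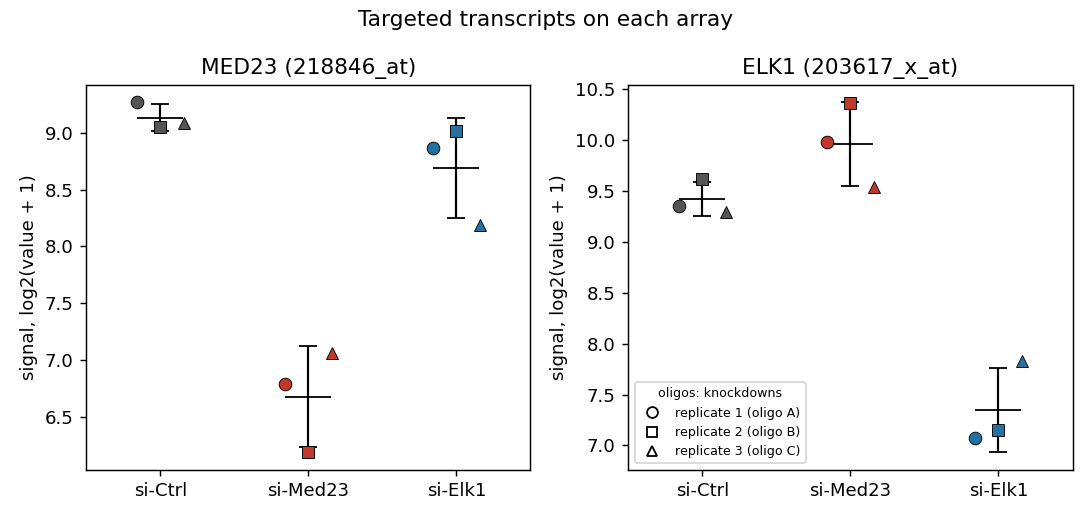
Log2 signal of the main MED23 and ELK1 probe sets on each of the 9 arrays by group, with the group mean and SD (n = 3); symbols mark the replicate, which in the knockdowns is the oligo. The si-Med23 arrays lie between 6.19 and 7.06 for MED23 and the si-Elk1 arrays between 7.07 and 7.83 for ELK1, below all control arrays.

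The control probe sets of the array differed between the groups, which bears on every direction given here. The mean log2 signal of the 24 poly-A spike probe sets, which report bacterial transcripts added to the RNA before labelling, was 7.61 ± 0.20 (SD, n = 3) in si-Ctrl, 9.22 ± 0.12 in si-Med23 and 8.25 ± 0.29 in si-Elk1. The 18 hybridization control probe sets read 11.83 ± 0.06, 12.33 ± 0.06 and 12.01 ± 0.10 in the same order, and the 3 probe sets for 18S ribosomal RNA read 7.87 ± 0.27 in si-Ctrl and 8.70 ± 0.32 in si-Med23, with si-Elk1 higher than si-Ctrl by 0.13 (exact permutation p = 0.6). All si-Med23 arrays lay above all control arrays in these measures, and the exact permutation p = 0.1 (2-sided) is the smallest that 3 arrays against 3 can give. The 3'/5' log2 differences of ACTB, a measure of RNA integrity, were 0.72 ± 0.13, 0.68 ± 0.07 and 0.67 ± 0.07. Scaling on the poly-A spikes would shift every log2 fold change by -1.61 in si-Med23, by -0.64 in si-Elk1 and by -0.97 between the knockdowns, scaling on the hybridization controls by -0.50, -0.18 and -0.32, and centring each array on its median by 0.23, -0.14 and 0.37. Directions are therefore given relative to the trimmed mean of each array, and the gene list tests compare a list with the other genes.

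**Figure D2:**
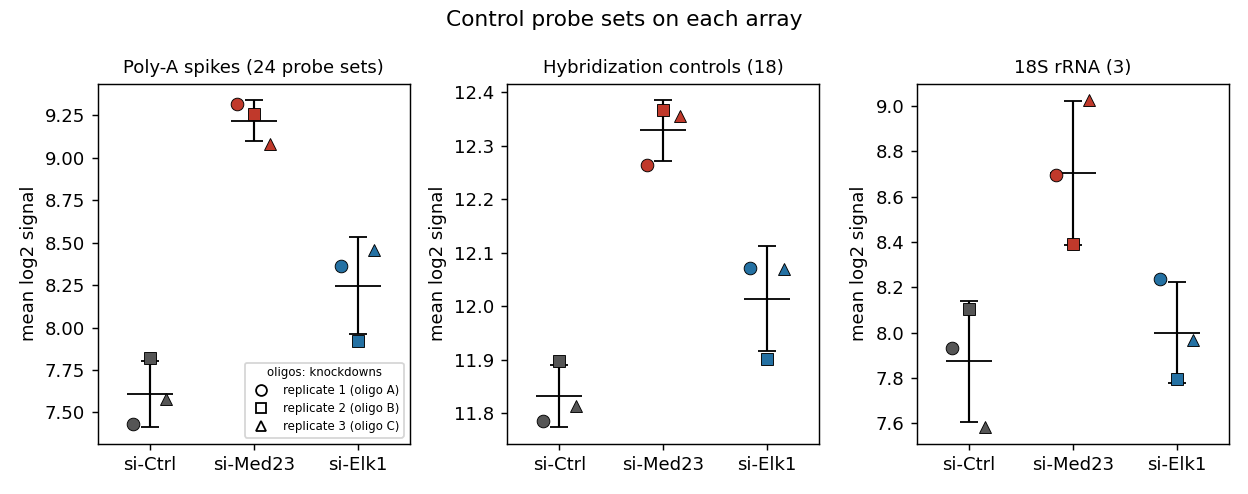
Mean log2 signal of the poly-A spike, hybridization control and 18S ribosomal RNA probe sets on each array by group, with the group mean and SD (n = 3); symbols mark the replicate, which in the knockdowns is the oligo. The si-Med23 arrays lie above the control arrays in each panel, by 1.61, 0.50 and 0.83 log2 units on average.

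The comparison of si-Med23 with si-Ctrl asked which transcripts depend on MED23. With the deposited scaling the lists of NF-kB and inflammatory genes and of mesenchymal genes rose relative to other genes, though both medians turn negative with poly-A spike scaling, and the list of mitotic genes fell, with a median that is negative under each scaling. None of these calls held with an estimated correlation (adjusted p = 0.627, 0.290 and 0.627), a setting that called no list in any comparison. The estimated correlation of the mesenchymal list, 0.0105, was near the preset 0.01, so correlation among its genes does not account for that loss. By fry, which does not set a list against other genes, the adjusted p-values were 0.00309, 8.54e-05 and 0.00309. C3, the central complement component, rose by a log2 fold change of 3.87 ± 0.36 (SE, n = 3 arrays per group). IL32, a pro-inflammatory cytokine, had a fitted change of 4.91 ± 0.48, but all its control signals lay below the filter level of log2 6.05, and raised to that level they give 3.70. CFB, complement factor B, rose by 2.93 ± 0.44. Of 36 genes of G2/M and mitosis 21 fell, among them TOP2A, a topoisomerase of chromosome segregation (-2.25 ± 0.32). In all, 2561 genes rose and 2462 fell, 39.8% of those tested, and the counts of list members below are to be read beside that share.

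Other large fitted rises were those of SERPINA6, which encodes corticosteroid-binding globulin (3.46 ± 0.31), the lysophospholipid transporter MFSD2A (3.37 ± 0.71), PDZK1IP1 (3.20 ± 0.39), the growth factor BMP4 (3.14 ± 0.45), LYPD1 (3.03 ± 0.40), the tight junction protein CGN (2.96 ± 0.32) and ZNF687 (2.85 ± 0.43). The largest fitted falls were those of the uncharacterized transcripts LOC221946 (-3.63 ± 0.54) and LINC00354 (-3.28 ± 0.63), BCAT1, a branched-chain amino acid transaminase (-3.21 ± 0.32), RIF1, a factor of DNA repair and replication timing (-3.08 ± 0.34), LINC01676 (-3.05 ± 0.86), and NTS, the precursor of neurotensin (-2.89 ± 0.23). THAP6 (-2.68 ± 0.51), the troponin gene TNNT3 (-2.62 ± 0.67), RALGAPA1, a subunit of a Ral GTPase-activating complex (-2.59 ± 0.44), and PHIP (-2.58 ± 0.31) fell as well. Adjusted p-values of these 20 genes ran from 0.00184 to 0.0230. In 7 of the 20 every array of the lower group lay below the filter level, so that their sizes and ranks are uncertain. With such signals raised to that level, an alternative added after the data were seen, the changes were 2.75 for SERPINA6, 1.57 for MFSD2A, 1.16 for CGN, -1.37 for LOC221946, -1.17 for LINC00354 and -1.42 for LINC01676. With 2 such arrays each, BMP4, CFB, ZNF687, THAP6 and TNNT3 came to 2.30, 2.51, 2.19, -2.08 and -0.96. LINC01676 lost its call without si-Ctrl replicate 2 or 3 (adjusted p = 0.0650 and 0.0638) and TNNT3 without si-Ctrl replicate 3 or si-Med23 oligo A (0.0536 and 0.0517). The other 18 kept theirs when any single array was left out.

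Of the 20 NF-kB and inflammatory genes tested, 14 rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone. The list's median log2 fold change was 1.46, which would be negative only under the poly-A spike scaling (camera adjusted p = 0.000133; adjusted p = 0.627 with an estimated correlation). Besides IL32, the neutrophil chemokine CXCL8 rose by 2.07 ± 0.22, the monocyte chemokine CCL2 by 1.84 ± 0.19 and LCN2, a siderophore-binding protein, by 2.57 ± 0.31. Among 22 interferon response genes 8 rose and 1 fell (median 0.49, adjusted p = 0.112), with the same counts adjusted over the list alone. These included ISG15, a ubiquitin-like modifier (1.52 ± 0.21), the signalling factor IRF9 (1.12 ± 0.15), IFI6 (1.58 ± 0.30) and IFITM1 (1.32 ± 0.27).

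The G2/M and mitotic list fell, with a median of -0.87 that stayed negative under each scaling (1 gene rose, 21 fell, 14 did not pass; adjusted over the list alone 2 rose and 21 fell). Its camera adjusted p was 0.000133 (adjusted p = 0.627 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, fell by 1.49 ± 0.16, the kinetochore gene NUF2 by 1.71 ± 0.20 and the checkpoint kinase gene TTK by 1.43 ± 0.19. The 36 G1/S and DNA replication genes went both ways, with 4 higher and 9 lower over all genes and over the list alone (median -0.03, adjusted p = 0.633). The clamp loader subunit RFC3 fell by 1.29 ± 0.20 and the polymerase subunit POLE2 by 1.18 ± 0.21, while the helicase subunit MCM5 rose by 0.72 ± 0.14. Of 20 p53 target genes 5 rose and 3 fell, likewise over the list alone (median 0.22, adjusted p = 0.810), with the cell cycle inhibitor CDKN1A higher by 0.89 ± 0.16 and the death receptor FAS lower (-1.11 ± 0.21). Of 20 apoptosis regulators 6 rose and 3 fell, likewise over the list alone (median 0.07, adjusted p = 0.810), among them BAD (0.64 ± 0.12) and CYCS, cytochrome c (-0.59 ± 0.11).

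The mesenchymal list rose, with a median of 0.64 that was negative only under the poly-A spike scaling (camera adjusted p = 0.00245; adjusted p = 0.290 with an estimated correlation, 0.101 with no filter and 0.0908 with the mean of all probe sets). Of its 15 genes tested 8 rose and 1 fell, and the same number did so adjusted over the list alone. SPARC, a collagen-binding matrix protein, rose by 2.27 ± 0.17, the collagen genes COL5A1 and COL1A1 by 1.89 ± 0.22 and 1.76 ± 0.19, and FN1, fibronectin, by 1.21 ± 0.13. The SRF-MRTF cytoskeletal list rose with a median of 0.44, negative under the poly-A spike and hybridization control scalings, and 8 of its 16 genes rose and 1 fell, likewise over the list alone. Its camera adjusted p was 0.0252 (adjusted p = 0.627 with an estimated correlation; 0.0677 without si-Med23 oligo B, 0.0552 with a stricter filter, 0.208 with the mean of all probe sets and 0.157 after quantile normalization). The LIM protein gene FHL2 was higher by 0.57 ± 0.13 and CALD1, caldesmon, lower (-0.95 ± 0.20). Of 18 TGF-beta target genes 9 rose and 4 fell, likewise over the list alone (median 0.41, adjusted p = 0.0973), among them LTBP2 (1.61 ± 0.23), TGFB1 (0.98 ± 0.15) and ID1 (0.66 ± 0.12). Of 18 epithelial genes 6 rose and 2 fell (6 and 3 over the list alone; median 0.23, adjusted p = 0.482), with the adhesion genes CDH1, E-cadherin (1.19 ± 0.21), and JUP, plakoglobin (1.05 ± 0.12), higher and the tight junction gene OCLN lower (-1.03 ± 0.24). Of 9 alveolar type II genes 4 rose, likewise over the list alone (median 0.45, adjusted p = 0.0753), including the surfactant lipid transporter gene ABCA3 (1.59 ± 0.24) and the lung transcription factor gene GATA6 (1.05 ± 0.15).

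Genes of Mediator and of the Ras pathway changed in both directions, in a comparison where 39.8% of all tested genes passed. Of 29 other Mediator subunit genes 9 rose and 8 fell (11 and 9 over the list alone), with a camera adjusted p = 0.926 and a median of 0.07 opposite in sign to the mean of -0.06. MED13, a kinase module subunit, fell by 1.67 ± 0.22 and the module's kinase CDK8 by 0.57 ± 0.10, whereas MED18 (0.99 ± 0.16) and MED16, another tail subunit (0.83 ± 0.15), rose. Of the 6 TCF and SRF factor genes 2 rose and 3 fell, likewise over the list alone (median -0.75, adjusted p = 0.482). ELK4, a paralog of ELK1, fell by 1.67 ± 0.32, the SRF coactivator MRTFB had a change of -0.99 ± 0.24 and its relative MRTFA one of 0.66 ± 0.15. Of 21 ERK pathway output genes 10 rose and 2 fell (11 and 3 over the list alone; median 0.55, adjusted p = 0.113), with SPRED1, an inhibitor of Ras signalling (-1.41 ± 0.15), and EREG, an EGF receptor ligand (-1.99 ± 0.29), lower and the cytokine IL11 (1.38 ± 0.26) higher. Of 21 immediate-early genes 6 rose and 1 fell, likewise over the list alone, with FOSL2 (1.03 ± 0.11) and JUNB (1.15 ± 0.24), both subunits of AP-1, higher; the median was -0.05, the mean 0.07 and the test upward (adjusted p = 0.814). Of 17 RAS-RAF-MEK-ERK components 4 rose and 4 fell (8 and 4 over the list alone; median 0.38, adjusted p = 0.482), with the kinase gene ARAF higher (0.80 ± 0.14) and the exchange factor gene SOS1 lower (-1.29 ± 0.23).

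Of 30 hypoxia and glycolysis genes 15 rose and 2 fell (16 and 2 over the list alone), and the list passed with a median of 0.38 that turned negative under the poly-A spike and hybridization control scalings (camera adjusted p = 0.0140; adjusted p = 0.627 with an estimated correlation; 0.165 after quantile normalization). EGLN3, an oxygen sensor, rose by 1.25 ± 0.22 and the glycolytic enzymes ALDOA, PKM and HK1 by 0.61 ± 0.13, 0.56 ± 0.12 and 0.78 ± 0.17. Of 33 cytosolic ribosomal protein genes 21 rose and none fell (26 over the list alone), for example RPL8 by 0.69 ± 0.12. Their median of 0.36 was -0.00494 after quantile normalization, where the call was lost (p = 0.811), and turned negative under the poly-A spike and hybridization control scalings (camera adjusted p = 3.35e-05; adjusted p = 0.685 with an estimated correlation). Of 23 sterol and fatty acid synthesis genes 6 rose and 4 fell (7 and 4 over the list alone; median 0.07, adjusted p = 0.810), with the sterol dehydrogenase NSDHL higher (0.94 ± 0.10) and the sterol transfer gene STARD4 lower (-1.68 ± 0.30). Of 24 NRF2 target genes 10 rose and 3 fell (11 and 4 over the list alone; median 0.29, adjusted p = 0.391), with the cystine transporter gene SLC7A11 lower (-1.71 ± 0.28) and GPX2, a glutathione peroxidase, higher (0.86 ± 0.17). Of 27 ATF4 and unfolded protein response genes 6 rose and 7 fell, likewise over the list alone, with a median of 0.03 and a mean of -0.07 (adjusted p = 0.810); the endoplasmic reticulum genes SDF2L1 (1.16 ± 0.20) and CRELD2 (1.29 ± 0.24) were higher and the amino acid synthesis genes ASNS (-1.28 ± 0.25) and PSAT1 (-0.86 ± 0.17) lower. Of markers of other cells, 1 of 6 haematopoietic genes rose, CD14, a lipopolysaccharide co-receptor (1.65 ± 0.25), likewise over the list alone (median -0.05, adjusted p = 0.926), and neither of the 2 endothelial genes tested, ROBO4 (-0.33) and PECAM1 (-0.08), passed (adjusted p = 0.814 for the list).

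**Figure D3:**
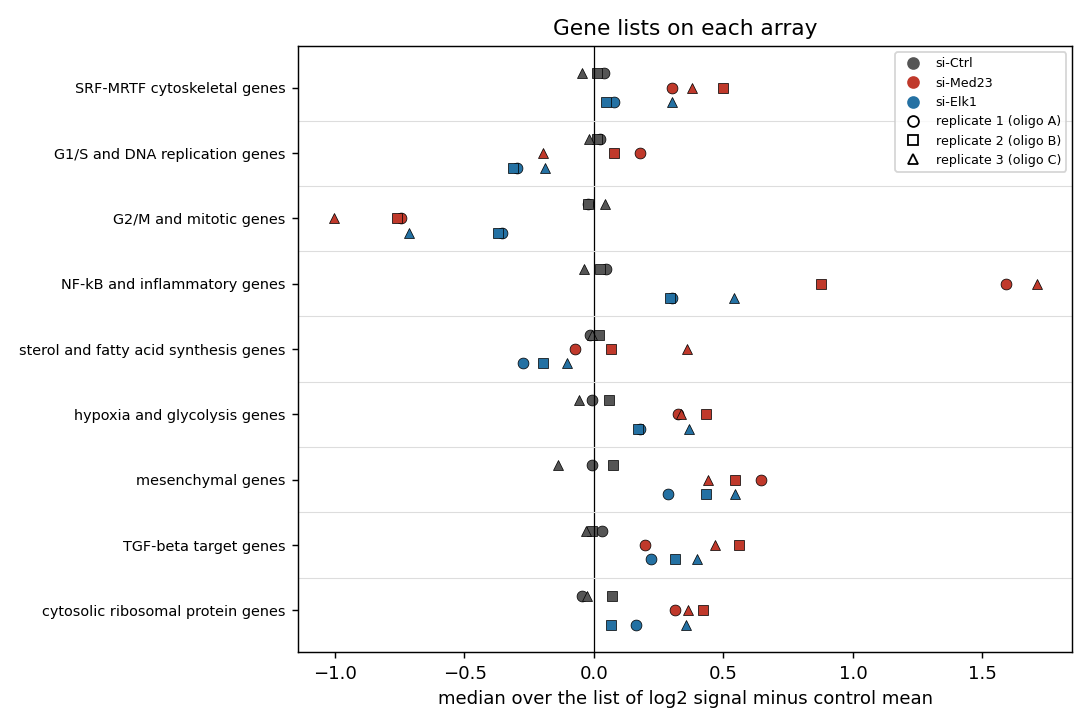
Median over each gene list of the log2 signal minus the control mean, per array, for the 9 lists that passed the camera test in either knockdown; colours mark the group and symbols the replicate, which in the knockdowns is the oligo. With the deposited scaling, the G2/M list lies below the control arrays on all 6 knockdown arrays and its median change is negative under each scaling, and the NF-kB list lies highest on the si-Med23 arrays, though its median change turns negative with scaling on the poly-A spikes.

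By limma with Benjamini-Hochberg adjustment, the 5023 genes changed in si-Med23 were 39.8% of those tested, with 465 higher and 1262 lower by at least 2-fold, and 6348 had an unadjusted p under 0.05. The 3 si-Med23 arrays did not overlap the 3 control arrays for 57.3% of genes, where chance gives 10%. The higher and lower counts were 2561 and 2462 as deposited, 4764 and 1676 after median centring, 409 and 5205 with hybridization control scaling and 18 and 11880 with poly-A spike scaling. Without si-Ctrl replicate 3 the count was 3174, and 6 of the 23 lists passed camera but none with an estimated correlation. Without probe sets whose names end in _x_at or _s_at, which can match several transcripts, the SRF-MRTF, mesenchymal, ribosomal and glycolysis lists did not pass (adjusted p = 0.205 for the first 3 and 0.50 for the last).

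The comparison of si-Elk1 with si-Ctrl asked which transcripts depend on ELK1. Knockdown of ELK1 changed fewer genes past the threshold, 387 higher and 150 lower. The largest fitted rises were those of NTS, the neurotensin precursor, at a log2 fold change of 3.68 ± 0.23 (SE, n = 3 arrays per group), TNS1, the focal adhesion protein tensin (3.48 ± 0.16), and ID4, an inhibitor of helix-loop-helix factors (3.07 ± 0.20). The largest fitted fall was that of KIRREL3, a cell adhesion molecule (-3.66 ± 0.42), but its si-Elk1 signals all lay below the filter level and give -2.42 when raised to it. GREM1, a BMP antagonist, fell by 2.12 ± 0.24. The lists of mitotic and DNA replication genes fell relative to other genes, with medians negative under each scaling, and the mesenchymal and TGF-beta lists rose, with medians negative only under poly-A spike scaling. None of these 4 calls held with an estimated correlation (adjusted p = 0.378, 0.436, 0.378 and 0.436). By fry, which does not set a list against other genes, the adjusted p-values were 0.0156, 0.0760, 0.00111 and 0.0161.

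Further rises were those of CES1, a carboxylesterase (2.90 ± 0.24), BMP4 (2.84 ± 0.45), CGN (2.82 ± 0.32), the matricellular gene SMOC1 (2.76 ± 0.56), NTRK3, a neurotrophin receptor (2.69 ± 0.32), ADGRV1 (2.63 ± 0.48) and C3 (2.62 ± 0.36). ELK1 itself was among the 10 largest falls, with LHFPL6 (-2.01 ± 0.29), MYBL1, a MYB family factor (-1.91 ± 0.31), BCAT1 (-1.85 ± 0.32), the small GTPase gene RRAD (-1.84 ± 0.39), CLTRN (-1.82 ± 0.18), EEA1, an early endosome tether (-1.79 ± 0.41), and EFNB2, ephrin-B2 (-1.68 ± 0.22). Adjusted p-values of these 20 genes ran from 9.89e-05 for TNS1 to 0.0494 for EEA1. Besides KIRREL3, every array of the lower group lay below the filter level for CGN, ADGRV1 and RRAD, whose changes were 1.01, 1.34 and -1.12 with those signals raised to it. BMP4 and SMOC1, with 2 such control arrays each, came to 2.00 and 2.59. NTS, TNS1, ID4, CES1, CGN, NTRK3, C3, KIRREL3, GREM1, ELK1, LHFPL6, CLTRN and EFNB2 kept the call when any single array was left out. BMP4 lost it without si-Ctrl replicate 3 or si-Elk1 oligo C (adjusted p up to 0.0532), and MYBL1 and BCAT1 lost it without si-Ctrl replicate 1, 2 or 3 (up to 0.0711 and 0.0803). SMOC1 lost it without si-Ctrl replicates 1 or 3 or any si-Elk1 oligo (up to 0.107) and ADGRV1 without si-Ctrl replicates 2 or 3 or si-Elk1 oligos A or C (up to 0.0924). RRAD lost it without any control or si-Med23 array or si-Elk1 oligo B (up to 0.127), and EEA1 without any array except si-Med23 oligo C (up to 0.143).

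Of 36 G2/M and mitotic genes 2 fell over all genes and 12 adjusted over the list alone, and none rose. The list's median was -0.44, negative under each scaling (camera adjusted p = 1.48e-08; adjusted p = 0.378 with an estimated correlation). Per array, the median relative to the control mean was -0.35, -0.37 and -0.71 with oligos A, B and C. The array of oligo C also departed from the other si-Elk1 arrays along the si-Med23 change, as described below. NUF2 and CDK1 fell (-0.95 ± 0.20 and -0.75 ± 0.16), but NUF2 lost its call without any single array and CDK1 without any except si-Med23 oligo B (adjusted p up to 0.133 and 0.124). CCNA2, cyclin A2, had a change of -0.71 ± 0.17 that did not pass. No G1/S and DNA replication gene passed, over all genes or over the list alone, but 34 of the 36 had a negative log2 fold change and the list's median was -0.27, negative under each scaling (camera adjusted p = 4.70e-06; adjusted p = 0.436 with an estimated correlation). The licensing factor CDC6 had a change of -0.47 ± 0.11 and MCM10 one of -0.82 ± 0.22. In the sterol and fatty acid synthesis list 1 of 23 genes fell, and 6 over the list alone (median -0.34, negative under each scaling; camera adjusted p = 0.00151; adjusted p = 0.436 with an estimated correlation). That gene was INSIG1, a sterol-sensing regulator (-1.04 ± 0.17; lost without si-Ctrl replicate 1 or 2 or si-Elk1 oligo A or C, adjusted p up to 0.0702). HMGCS1, an enzyme of the mevalonate pathway, had a change of -0.78 ± 0.21 (adjusted p = 0.0729).

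The mesenchymal list rose, with 5 of 15 genes higher and none lower (6 and 1 over the list alone). Its median was 0.49, negative only under the poly-A spike scaling (camera adjusted p = 0.0185; adjusted p = 0.378 with an estimated correlation; 0.0641 without si-Elk1 oligo A, 0.108 with no filter and 0.211 with the mean of all probe sets). The gelatinase gene MMP2 rose by 1.87 ± 0.15, SPARC by 1.79 ± 0.17 and FN1 by 1.28 ± 0.13. The TGF-beta target list rose with a median of 0.36, negative only under the poly-A spike scaling (3 of 18 genes higher, 6 over the list alone, none lower; camera adjusted p = 0.00980; adjusted p = 0.436 with an estimated correlation and 0.114 with the mean of all probe sets). ID1 and ID3, targets of BMP signalling, rose by 0.93 ± 0.12 and 0.76 ± 0.13 alongside BMP4. ID3 lost its call without si-Ctrl replicate 1, 2 or 3 (adjusted p up to 0.0830) and BMP4 without si-Ctrl replicate 3 or si-Elk1 oligo C (up to 0.0532). The hypoxia and glycolysis list rose with a median of 0.21, negative only under the poly-A spike scaling (4 of 30 genes higher, 6 over the list alone, none lower; camera adjusted p = 0.00113; adjusted p = 0.436 with an estimated correlation). EGLN3 rose by 1.66 ± 0.22 and the glucose transporter gene SLC2A3 by 0.99 ± 0.15, the latter lost without si-Ctrl replicate 1, 2 or 3 (adjusted p up to 0.0609). None of the 33 ribosomal protein genes passed, over all genes or the list alone, but all 33 had a positive change and the list rose with a median of 0.19, negative under the poly-A spike scaling (camera adjusted p = 0.00113; adjusted p = 0.928 with an estimated correlation; 0.855 after quantile normalization and 0.0531 after median centring).

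The remaining lists did not pass in si-Elk1. Of 18 epithelial genes 2 rose and 2 fell, likewise over the list alone. PKP2, a desmosomal protein, fell (-1.61 ± 0.20), and the list's median of 0.09 differed in sign from its mean of -0.09 (adjusted p = 0.858). Of 20 NF-kB and inflammatory genes 2 rose and 1 fell (6 and 1 over the list alone; median 0.42, adjusted p = 0.239), namely LCN2 (1.73 ± 0.31), CCL20 (2.55 ± 0.53) and CCL2 (-0.88 ± 0.19). Of 21 immediate-early genes, among which ELK1 has known targets, 1 rose and 2 fell (4 and 3 over the list alone; median 0.25, adjusted p = 0.858), namely ZFP36 (1.00 ± 0.19), KLF6 (-0.68 ± 0.16) and KLF4 (-0.74 ± 0.17). None of 21 ERK pathway output genes passed over all genes, and 5 rose and 3 fell over the list alone (median -0.08, adjusted p = 0.858). Of the 6 TCF and SRF factor genes MYOCD rose (1.87 ± 0.32), also over the list alone, with a list median of -0.08 and mean of 0.20 (adjusted p = 0.885). Of the Mediator subunits MED21 fell (-0.54 ± 0.11), also over the list alone (median -0.01, adjusted p = 0.241). Among the Ras pathway components RRAS2 fell (-0.61 ± 0.11), also over the list alone (median 0.09, adjusted p = 0.858). Of the haematopoietic markers CD14 rose by 1.77 ± 0.25, and 2 of 6 rose over the list alone (median 0.64, adjusted p = 0.274). Of the SRF-MRTF list 1 of 16 genes fell, CCN2 (-0.67 ± 0.13), and 3 rose and 1 fell over the list alone (median 0.14, adjusted p = 0.858). MDM2 was the p53 target that fell (-0.68 ± 0.13, but 0.11 without probe sets that can match several transcripts; 3 higher and 1 lower over the list alone; median 0.05), and BCL2L1 the apoptosis regulator that rose (0.60 ± 0.14; 1 over the list alone; median 0.01, test downward). Among ATF4 and unfolded protein response genes DDIT4 (1.01 ± 0.20) and XBP1 (0.72 ± 0.15) rose (3 higher and 2 lower over the list alone; median -0.08). No interferon response, NRF2 target, alveolar type II or endothelial gene passed, over all genes or over the list alone, with medians of 0.21, 0.09, 0.17 and 0.06, the last with a downward test. These 7 lists had adjusted p-values between 0.858 and 0.943. Of the genes named here only PKP2 kept its call when any single array was left out. CD14 lost it without si-Ctrl replicate 3 (adjusted p = 0.0511) and MYOCD without si-Ctrl replicate 1 or si-Elk1 oligo A or B (up to 0.0646). The others lost it without si-Ctrl replicate 1, 2 or 3 and without at least 2 si-Elk1 oligos, with adjusted p between 0.0517 and 0.146.

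By limma with Benjamini-Hochberg adjustment, the 537 genes changed in si-Elk1 were 4.26% of those tested, with 174 higher and 57 lower by at least 2-fold, and 3162 had an unadjusted p under 0.05. The si-Elk1 and control arrays did not overlap for 36.3% of genes, where chance gives 10%. The higher and lower counts were 387 and 150 as deposited, 239 and 328 after median centring, 166 and 258 with hybridization control scaling and 95 and 4898 with poly-A spike scaling. The count fell to 148, 154 and 109 without si-Ctrl replicates 1, 2 and 3, to 199, 250 and 265 without si-Elk1 oligos A, B and C, and to 119 with no filter on dim genes. Without probe sets that can match several transcripts the mesenchymal, TGF-beta, ribosomal and glycolysis lists did not pass (adjusted p = 0.635, 0.415, 0.260 and 0.163).

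Whether the knockdowns changed the same transcripts was asked next. The complement genes C3 and CFB, BMP4, the tight junction gene CGN, SMOC1, the chemokine CCL20, SERPINA6, the coronin CORO2A, the small GTPase gene RAB20 and MST1, which encodes macrophage-stimulating protein, had the largest changes called in both, and all 10 rose in both. CORO2A rose by 2.13 ± 0.23 in si-Med23 and by 2.19 ± 0.23 in si-Elk1 (SE, n = 3 arrays per group), and CCL20 by 2.19 ± 0.53 and 2.55 ± 0.53. The control signals of CORO2A, CGN and SERPINA6 all lay below the filter level, and raised to it they give 1.38, 1.16 and 2.75 in si-Med23 and 1.45, 1.01 and 1.44 in si-Elk1. For BMP4, CFB, SMOC1 and MST1, with 2 such control arrays each, the values were 2.30, 2.51, 2.12 and 1.49 in si-Med23. In si-Elk1 they were 2.00, 1.92, 2.59 and 1.70. CFB was higher by 2.34 ± 0.44 in si-Elk1, RAB20 by 2.62 ± 0.42 and 2.12 ± 0.42, and MST1 by 1.95 ± 0.37 and 2.15 ± 0.37. In si-Elk1 the calls of C3, CGN and CORO2A were kept when any single array was left out, and those of SERPINA6 and BMP4 were lost without si-Ctrl replicate 3 and, for BMP4, without oligo C (adjusted p up to 0.0522 and 0.0532). Those of CFB, SMOC1, CCL20, RAB20 and MST1 were lost without each of at least 4 arrays taken singly, si-Elk1 oligos A and C among them (adjusted p up to 0.0908, 0.107, 0.0984, 0.0913 and 0.0680).

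In all 255 genes rose in both knockdowns and 92 fell in both, where independent lists of these sizes would share 78.6 and 29.3, and 14 changed in opposite directions against 106 for independent lists. The shared genes were 64.6% of those called in si-Elk1. Both comparisons use the same control arrays, which raises agreement by itself. The log2 fold changes correlated across the 12616 genes with r = 0.577 (Spearman 0.567), against a mean of 0.502 and a maximum of 0.541 in 100 simulations of unchanged groups with shared controls, and genes are not independent replicates. The covariance was 0.201 against 0.0333 simulated, and 71.9% of genes had the same sign against 66.7%. With the controls split so that the knockdowns shared none, 1 array for one and 2 for the other, an alternative added after the data were seen, the covariance lay between 0.150 and 0.199 and r between 0.376 and 0.490 over the 6 assignments. Part of the excess in shared calls may come from the shared controls. In the poly-A spikes and hybridization controls all arrays of both knockdowns lay above all control arrays. The lowest si-Elk1 array read 7.92 and 11.900, and the highest control array 7.82 and 11.897. Shared changes from handling that differed between knockdowns and controls would not be removed by the simulations or by the split of the controls. They were not tested apart from effects of the knockdowns. The 347 shared genes became 104, 115 and 75 without si-Ctrl replicates 1, 2 and 3 and 150, 176 and 178 without si-Elk1 oligos A, B and C. Without oligo C the correlation was 0.41, below the mean of 0.448 in 100 simulations of that setting. In the simulations no gene was changed, so their r and share of same signs come from noise around shared controls. They are no measure for arrays on which many genes changed, and no conclusion is drawn from r or from that share, with or without oligo C. The covariance without oligo C was 0.131 against 0.0279 simulated. Of the 265 genes then called in si-Elk1, 178 genes (67.2%) were shared, where independent lists would share 63.0 genes.

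**Figure D4:**
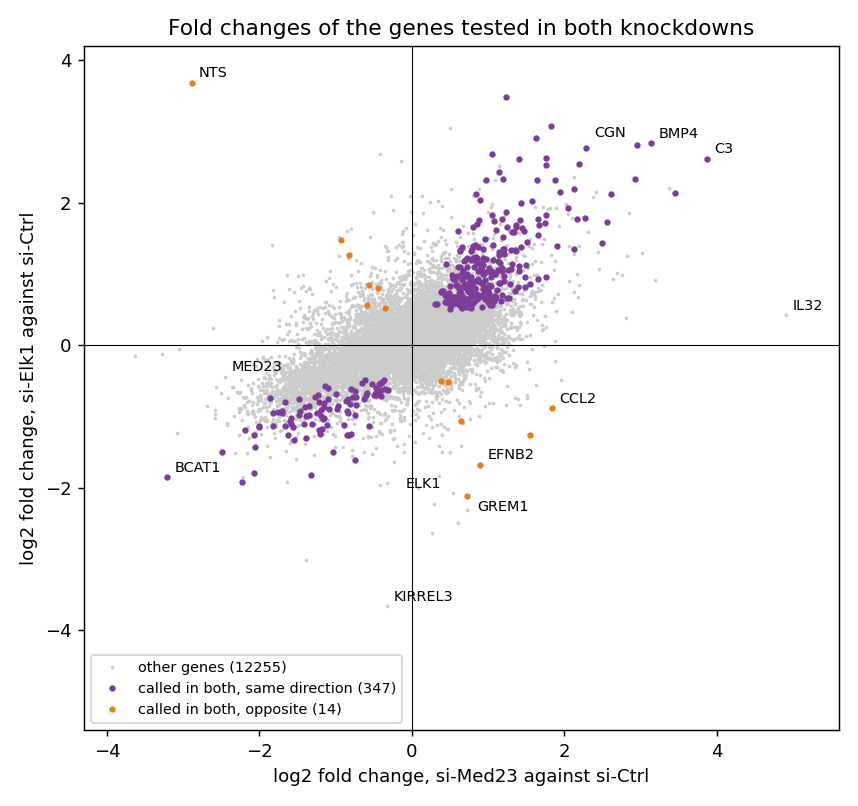
Log2 fold change of each tested gene in si-Elk1 (vertical axis) against that in si-Med23 (horizontal axis), both relative to si-Ctrl. The 347 genes called in both in the same direction and the 14 called in opposite directions are coloured, and NTS lies at -2.89 in si-Med23 and 3.68 in si-Elk1.

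The direct comparison of si-Med23 with si-Elk1 asked where the knockdowns differ. NTS had the largest fitted difference, with a log2 fold change of -6.57 ± 0.23 in si-Med23 relative to si-Elk1 (SE, n = 3 arrays per group; limma adjusted p = 1.04e-05). IL32 was higher in si-Med23 (4.48 ± 0.48), as were KIRREL3 (3.33 ± 0.42), the protocadherins PCDH10 (3.10 ± 0.67) and PCDH7 (3.03 ± 0.57), and GREM1 (2.84 ± 0.24). LOC221946 (-3.48 ± 0.54), RTN4RL2, a Nogo receptor relative (-3.25 ± 0.48), LINC00354 (-3.16 ± 0.63) and the mucin gene MUC5B (-3.10 ± 0.91) were lower in si-Med23. The inflammatory and sterol synthesis lists were higher in si-Med23 with the deposited scaling, and their medians turn negative with poly-A spike scaling and, for the sterol list, with hybridization control scaling. Neither call held with an estimated correlation (adjusted p = 0.557 for both), and by fry, which does not set a list against other genes, the adjusted p was 0.0265 for both. Every array of the lower knockdown lay below the filter level for IL32, KIRREL3, LOC221946 and LINC00354, whose differences were 3.70, 2.09, -1.21 and -1.05 with those signals raised to it. With 2 such arrays each, PCDH10, PCDH7 and MUC5B came to 1.72, 2.14 and -1.83. The call of PCDH10 was lost without oligo A or B of either knockdown (adjusted p up to 0.0661), that of MUC5B without any array except si-Ctrl replicate 3 and si-Med23 oligo C (adjusted p up to 0.118), and that of LINC00354 without si-Elk1 oligo A (0.0512).

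Of 20 NF-kB and inflammatory genes 9 were higher in si-Med23 and none lower (11 and 1 over the list alone), with CCL2 at 2.72 ± 0.19 and CXCL2, another neutrophil chemokine, at 1.37 ± 0.23. The list's median was 0.75, negative only under the poly-A spike scaling (camera adjusted p = 0.000267; adjusted p = 0.557 with an estimated correlation). Of 23 sterol and fatty acid synthesis genes 8 were higher and 1 lower, likewise over the list alone, with INSIG1 at 1.09 ± 0.17 and NSDHL at 0.84 ± 0.10 (median 0.28, negative under the poly-A spike and hybridization control scalings; camera adjusted p = 0.00498; adjusted p = 0.557 with an estimated correlation). These 2 lists kept their call without any single array. Another 6 lists passed, all higher in si-Med23, and each lost its call without at least 1 array: ribosomal protein genes (median 0.18; camera adjusted p = 0.00498; adjusted p = 0.695 with an estimated correlation), G1/S and DNA replication genes (0.23; 0.0425; adjusted p = 0.646 with an estimated correlation), SRF-MRTF genes (0.23; 0.0427), interferon response genes (0.22; 0.0427), alveolar type II genes (0.54; 0.0427) and epithelial genes (0.22; 0.0443), the last 4 with adjusted p = 0.557 with an estimated correlation. All 6 medians turn negative under the poly-A spike scaling and all but that of the alveolar list under the hybridization control scaling, and the ribosomal median was -0.0121 after quantile normalization, where its call was lost (adjusted p = 0.638). Calls were also lost for SRF-MRTF, G1/S and epithelial genes after quantile normalization (adjusted p from 0.104 to 0.155), for these and interferon genes with a stricter filter (0.137 to 0.280), and for SRF-MRTF, interferon, epithelial and alveolar genes after median centring (0.0540 to 0.125). With the mean of all probe sets all 6 but G1/S were lost (0.0553 to 0.284), and without probe sets that can match several transcripts all 6 but alveolar (0.0549 to 0.479, with an epithelial median of -0.19). Interferon genes lost theirs with no filter (0.191), and interferon, epithelial and alveolar genes with array weights (0.0652 to 0.179). Epithelial genes also lost theirs with the replicate number as a block. The arrays whose omission ended a call were si-Elk1 oligo B for ribosomal, G1/S, SRF-MRTF, alveolar and epithelial genes, si-Elk1 oligo A for SRF-MRTF, interferon and alveolar genes, and si-Elk1 oligo C for G1/S, interferon, alveolar and epithelial genes. They were also si-Med23 oligo A for G1/S genes, oligo B for G1/S, SRF-MRTF, alveolar and epithelial genes, and oligo C for SRF-MRTF, interferon, alveolar and epithelial genes, with adjusted p between 0.0501 and 0.188. Within these lists the cytokeratin gene KRT19 was higher by 2.10 ± 0.37, GATA6 by 1.05 ± 0.15, ISG15 by 1.19 ± 0.21, MCM5 by 0.90 ± 0.14 and CCN2, a matricellular growth factor, by 0.83 ± 0.13. Over all genes and over the list alone, members higher and lower were 1 and 0, then 0 and 0, for ribosomal proteins, 7 and 3, then 8 and 3, for G1/S, 5 and 1, then 7 and 1, for SRF-MRTF, 4 and 0, then 3 and 0, for interferon, 3 and 0, then 4 and 0, for alveolar and 5 and 0 both times for epithelial genes.

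The other 15 lists had adjusted p-values between 0.0760 and 0.956, and 8 of them had a median, mean and test that differed in sign. Among the ERK pathway output genes, 8 of 21 were higher in si-Med23 and 3 lower, likewise over the list alone, with the ephrin receptor gene EPHA4 at 1.80 ± 0.30 (1.00 with its si-Elk1 signals, all below the filter level, raised to it) and the feedback inhibitor SPRY1 at 0.94 ± 0.17. Of the Mediator subunits 8 were higher and 4 lower (10 and 6 over the list alone), with MED18 at 0.84 ± 0.16. MYOCD was lower in si-Med23 (-2.37 ± 0.32), as were the nuclear receptor gene NR4A2 (-1.18 ± 0.17) and VLDLR (-0.83 ± 0.12), while the matrix genes TNC (1.68 ± 0.29) and COL5A1 (1.40 ± 0.22) and the apoptosis gene BAD (0.90 ± 0.12) were higher. By limma 1204 genes were higher and 1535 lower in si-Med23 than in si-Elk1, 21.7% of those tested, 5009 had an unadjusted p under 0.05, and the arrays did not overlap for 38.0% of genes, where chance gives 10%. The split was 4711 higher and 553 lower after median centring, 359 and 3943 with hybridization control scaling and 33 and 10219 with poly-A spike scaling. The count was 1629 and 1338 without si-Med23 oligos A and B, 769 and 896 without si-Elk1 oligos A and B, and 4496 without si-Elk1 oligo C.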

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

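The tests of the spike and ribosomal RNA signals reported here were chosen after those signals were seen, and the counts over other splits of the arrays were planned before.

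Signals of the added controls were higher in both knockdowns than in si-Ctrl, and those of ribosomal RNA were higher in si-Med23. The poly-A spike probe sets were higher by 1.61 log2 units in si-Med23, where 24 of 24 rose by 0.92 to 2.18, and by 0.64 in si-Elk1. In si-Med23 the hybridization control probe sets were higher by 0.50 and the mean of the 6 ribosomal RNA probe sets by 0.66. In si-Elk1 that ribosomal RNA mean was higher by 0.097, and the arrays overlapped the control arrays for 18S and 28S ribosomal RNA.

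More spike RNA in the si-Med23 samples and nothing else would leave ribosomal RNA within the control range, and its rise of 0.658 on average argues against that as the whole cause. The hybridization controls rose by 0.497 on the same arrays, so much of the ribosomal RNA rise may be array-wide. Ribosomal RNA was not tested beyond that rise, and more spike together with an array-wide rise stays open. Array scaling or hybridization alone would raise both kinds of added control alike, and the spikes rose by 1.11 more than the hybridization controls, which argues against that as the whole cause too. A lower share of polyadenylated RNA in total RNA may raise both the spikes and ribosomal RNA. The median ribosomal RNA probe set rose by 0.737, with the rise of the hybridization controls not taken off, but 1 of the 6 had a change of -0.50. The amounts of RNA and spike used are not given in the sources used here. A lower polyadenylated share, with more spike beside another cause, stays open and cannot be told apart from handling that differed between the groups. A change in total messenger RNA after MED23 knockdown is therefore an untested hypothesis, and it would need the amount of RNA per cell.

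Tests of the difference between the knockdowns singled out 8 gene lists and 4 genes. By camera, NF-kB and inflammatory genes (adjusted p = 0.000267), sterol and fatty acid synthesis genes (0.00498), ribosomal protein genes (0.00498), G1/S and DNA replication genes (0.0425), SRF-MRTF genes (0.0427), interferon response genes (0.0427), alveolar type II genes (0.0427) and epithelial genes (0.0443) were higher in si-Med23 than in si-Elk1, and none passed with an estimated correlation. After median centring 4 lists passed. By limma NTS differed by -6.57, GREM1 by 2.84, CCL2 by 2.72 and EFNB2 by 2.57 log2 units, si-Med23 minus si-Elk1, each with called changes against si-Ctrl of opposite sign in the knockdowns, from which the pass of the difference follows.

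With 3 arrays against 3 there are 10 splits, too few for a share under 0.1. The real split gave 5023 genes in si-Med23 against si-Ctrl and the highest other 0, with 537 and 1 in si-Elk1 against si-Ctrl and 2739 and 1 in si-Med23 against si-Elk1.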

How the results depend on the processing

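The spike and hybridization control scalings, adjustment of the targeted genes over the tested genes, raising signals to the filter level and splitting the controls were chosen after the data were seen, and the other alternatives before. Of 329 results for named genes, 156 kept their direction and side of the threshold in all alternatives run. Over all settings 6056 of 7025 gene values kept both, 777 lost the call (451 of them with an array left out), 181 gained it and 11 reversed. For called lists, 427 of 525 values kept both, 96 lost the call and 2 reversed. Of the values kept, 329 for genes and 21 for lists belong to the setting of at least 1.5-fold. It bore only on counts of genes, so these values were kept by construction, and an adjusted p under 0.1 could lose no call. With signals under the filter level raised to it, 301 of 329 sizes moved by less than 1 SD and none reversed. Dim genes sit near the background of the arrays, and causes were not tested except where fewer genes or arrays follow from the setting.

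Counts of genes changed that moved by over 1.5 times are given for si-Elk1 against si-Ctrl, then si-Med23 against si-Elk1, then both knockdowns alike. They were 119, 979 and 81 with no filter, 271, 1783 and 199 with the mean of all probe sets, 1594, 4966 and 889 with array weights, and 1506, 4358 and 990 at an adjusted p under 0.1. With poly-A spike scaling they were 4993, 10252 and 4864, and si-Med23 against si-Ctrl gave 11898. For si-Elk1 against si-Ctrl and both alike they were 937 and 660 with the stricter filter, 318 and 207 without probe sets ending in _x_at or _s_at, and 1064 and 733 with a trended and robust prior. Si-Med23 against si-Elk1 gave 5264 after median centring, 4302 with hybridization control scaling and 1074 in a fit of 6 arrays.

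Gene lists called in si-Med23 against si-Elk1 were 4 with the stricter filter, quantile normalization or median centring, 3 with the mean of probe sets or without _x_at and _s_at probe sets, and 5 with array weights. In si-Med23 against si-Ctrl they were 3 without those probe sets or after quantile normalization, and in si-Elk1 3 without those probe sets. With an estimated correlation 0 were called in any comparison, whatever correlation was estimated for a list (from -0.13 to 0.84). Fry called 13 in si-Med23 against si-Ctrl, and its mixed test 22, 20 and 22. The correlation of the knockdowns' fold changes was 0.43 with array weights.

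Reversals with the mean of all probe sets were VCL -0.32, SC5D 0.20, FOXA2 -0.085 and RPS9 -0.16 in si-Med23 against si-Ctrl, and CCNC 0.040, VCL -0.42, GINS2 -0.37 and BIRC5 0.44 against si-Elk1. Without _x_at and _s_at probe sets they were MDM2 0.11 in si-Elk1 and GINS2 -0.086 and PARP9 -0.54 between the knockdowns. After quantile normalization the ribosomal list's median was -0.00494 in si-Med23 against si-Ctrl and -0.0121 between the knockdowns. The ELK1 change of -2.07 passed when adjusted over the tested genes. ELK1 has no value without _x_at and _s_at probe sets.

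With 1 array left out, counts of genes changed ranged from 3174 to 5884 in si-Med23 against si-Ctrl, 109 to 498 in si-Elk1 against si-Ctrl, 769 to 4496 between the knockdowns and 75 to 291 in both. The lists called ranged from 5 to 7, 6 to 8 and 3 to 8, the correlation from 0.41 to 0.62, and the MED23 and ELK1 changes from -2.65 to -2.21 and from -2.31 to -1.93.

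The replicate numbers do not pair the samples: residuals of arrays with the same number correlated between -0.18 and 0.05. With the replicate number as a block the counts were 162, 1319 and 114 in the order above, and the MED23 change of -2.46 had an adjusted p of 0.0882, and the epithelial list's call between the knockdowns was lost (0.0550).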

Other observations

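The 14 genes called in opposite directions were singled out after their values were seen, as were the tests of MED23 and of the spike signal for si-Elk1 oligo C. The other tests were planned before, but the margins by which 2 of them had to pass were added after, and both made the wording weaker.

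Of the 14 genes, 7 were lower in si-Med23 and higher in si-Elk1 than in si-Ctrl. Besides NTS these were SCG2, secretogranin II (log2 fold change -0.94 in si-Med23 and 1.48 in si-Elk1), NAT16 (-0.83 and 1.26), DIXDC1, a regulator of Wnt signalling (-0.59 and 0.57), ANKRD20A12P (-0.56 and 0.85), the phospholipid transporter gene ATP10B (-0.45 and 0.81) and PLEKHG4 (-0.36 and 0.52). NTS and SCG2 both encode products of regulated secretory granules. The 7 that were higher in si-Med23 and lower in si-Elk1 were CCL2 (1.84 and -0.88), OLFML3, a secreted matrix protein (1.56 and -1.26), EFNB2 (0.89 and -1.68), GREM1 (0.72 and -2.12), the transcription factor TOX3 (0.65 and -1.06), PEA15, which binds ERK in the cytoplasm (0.48 and -0.52), and CORO1C (0.38 and -0.49). Many passed narrowly. In si-Elk1 the limma adjusted p was 0.000402 for NTS, 0.00570 for GREM1, 0.00817 for EFNB2 and 0.0132 for ATP10B. For the others it lay between 0.0271 and 0.0461, and in si-Med23 it ran from 0.00184 to 0.0452. CCL2 lost its si-Elk1 call without any single control array, si-Med23 oligo B, or si-Elk1 oligo A or C (adjusted p up to 0.126). Independent lists would give 30.4 genes higher in si-Med23 and lower in si-Elk1 and 75.5 the other way.

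The array of si-Elk1 oligo C departed from the other si-Elk1 arrays along the change seen in si-Med23, with r = 0.53 across genes, which are not independent replicates. After quantile normalization r was 0.525, which argues against signal-dependent scaling as the cause. A candidate explanation is that this oligo also lowered MED23, whose main probe set differed by -0.759 log2 units from the mean of the other 2 si-Elk1 arrays while all 3 si-Elk1 arrays lay below every control array. MED23 is itself among the genes that fell in si-Med23, so any departure along that change would lower it. Its difference was 0.309 of its si-Med23 change, where the slope over all genes was 0.41, so it gives no separate support for this explanation. The other MED23 probe sets with control means above the filter level also read lowest of the group on this array. They gave 6.82 against 7.72 and 8.04, and 7.41 against 7.68 and 7.96, and the 7.41 lay within the control range of 6.36 to 7.86. Those with control means below that level, 5.80 and 4.97, read highest on it. Any departure along the si-Med23 change would lower these probe sets too. The ELK1 signal of this array, 7.83, was the highest of the group, against 7.07 and 7.15. RNA input or labelling as on the si-Med23 arrays cannot be told apart, since its spike signal was 0.316 higher than that mean where 0.660 was needed.

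Ribosomal protein and glycolysis genes are bright, and the brightest 2523 genes had a median log2 fold change of 0.19 in si-Med23 against -0.10 for the dimmest 2524. Among 10000 random lists matched on signal, the ribosomal list's median lay at percentile 71.9 in si-Med23 and 96 in si-Elk1, so signal-dependent scaling may account for both rises. The glycolysis list lay at 99.2 in si-Elk1, with a median of 0.209 against an upper bound of 0.189. In si-Med23 it lay at 97.7, too near the upper bound of the matched lists to decide. The random lists were drawn gene by gene, while this list's genes had an estimated correlation of 0.17. Medians of correlated genes vary more than such lists show, so the si-Elk1 value does not decide either. Without probe sets that can match near-identical copies, the 17 ribosomal protein genes left had a median of 0.359 with a bootstrap interval from -0.14 to 0.45, which leaves that explanation open. A biological rise of these lists was not tested apart from scaling.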
